A study of Mus musculus with 6 samples.

How the data were processed

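Gene expression was measured on 6 arrays of macrophages sorted from mouse heart allografts, 3 from recipients treated with mTORi-HDL and 3 from untreated recipients. The deposited table holds log2 expression values for 41345 probe sets per array, made with Affymetrix Expression Console and RMA per the submitters' processing notes, which name no versions. RMA as a method corrects background, quantile-normalizes probes and summarises them into probe sets on the log2 scale. The genome build, the probe-set filters and the sort markers were not given in the sources used here, and no genomic coordinates are printed. The table had 0 missing values and 0 pairs of arrays with identical values. Per the labels, 15 ng of RNA was amplified for each array with a whole-transcriptome protocol for small inputs. Array intensities have no read depth, and the number of arrays limits the precision.

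Probe sets were named through the platform annotation: 23521 had 1 gene symbol, 1814 had several and 16010 had none. Only those with 1 symbol entered the comparison, and the brightest one stood for each of 1082 genes with more than 1, which left 22180 genes. Gene identifiers of 23328 of the named probe sets were found in a RefSeq table of assembly GRCm38.p6, used for names only, and 0 of these had another symbol there. No filter on dim genes and no further normalization was applied. Treated and untreated arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment over all genes, two-sided. Fold changes are treated minus untreated on the log2 scale.

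Before the data were examined 30 gene lists were fixed, 19 of pathways and macrophage states and 11 of cell types that the sort could hold. Of their 860 entries 775 were measured, 2 of them found through a gene identifier, 37 lay only on probe sets of several genes, and 48 were not analysed here. Lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 30 lists, with an estimated correlation and with fry beside it. Camera compares a list with all other genes, and fry asks whether a list's own genes move one way on balance. The count of members "adjusted over the list alone" applies Benjamini-Hochberg within the list. Named genes followed a rule fixed before the data were examined: the 10 genes per direction with the largest change among those that passed and did not overlap between groups (or, since fewer than 5 passed, the 10 with the smallest p, which did not pass), up to 4 members per list with the smallest p, and a panel of 32 genes. Uninformative symbols, small RNAs and receptor segments were left out of the first part. Pltp was named after its values were seen.

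The test was tried on simulated arrays of the 22180 genes, written after the first run of the real comparison, with 200 genes changed in each of 10 simulations. With 6 ordinary arrays it recovered 27.6%, 95.2%, 99.8% and 99.8% of genes changed by 2, 4, 8 and 16 times. With 1 array compressed as mTORi-HDL 1 was, it recovered 0%, 13%, 41.8% and 53.2%. With that array left out it recovered 5.2%, 89.4%, 98.6% and 99.6%. On average 12.6 of 183.7, 0.5 of 54.5 and 11.4 of 162.2 called genes were false, in that order. The simulated genes varied independently, with variances that limma had already drawn together, so these shares need not hold for the real arrays. There, without mTORi-HDL 1, Kif11 had a log2 fold change of -2.76 and did not pass (limma, adjusted p = 0.121). A cell cycle list shifted by 1 on the log2 scale was called in 100% of simulations with 6 ordinary arrays and with the compressed array left out. With the compressed array this says nothing, since the list was called there without any shift.

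Alternatives fixed before the data were examined were median centring, quantile normalization, filters at the median and at the 25th percentile of brightness, eBayes with trend and robust, array weights, the replicate number as a block, each array left out in turn, the mean of a gene's probe sets, all probe sets, other thresholds, an estimated correlation, camera on ranks, fry, and lists without shared members. Cyclic loess and 4 settings that leave out mTORi-HDL 1 together with another choice were added after the data were seen. Probe sets with several or no symbols, 17634 in all without control probe sets, were tested separately: 0 passed limma's test at an adjusted p of 0.05 and 665 had an unadjusted p under 0.05.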

Results

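Hearts of BALB/c mice had been transplanted into C57BL/6 recipients, and macrophages that had entered the grafts were sorted by flow cytometry on day 6. The recipients of 3 samples had received mTORi-HDL, a nanoparticle that carries an mTOR inhibitor in high-density lipoprotein, at 5 mg/kg on days 0, 2 and 5. The recipients of the other 3 samples were untreated and rejected their grafts. No sample came from recipients of the lipoprotein without the inhibitor, so effects of the inhibitor and of its carrier cannot be told apart. Each sample was hybridised to 1 array after amplification from 15 ng of RNA, and each array gave 41345 log2 values, from which 22180 named genes were compared. The 6 arrays set the precision, and the labels do not say whether each sample came from 1 recipient or from a pool. The array named mTORi-HDL 1 stood apart from the rest: its values had an SD of 1.68, against 2.04 to 2.09 on the other 5 arrays. It correlated with them across probe sets at r = 0.708 to 0.741, where the other 5 correlated with each other at 0.892 to 0.912. Its values against the mean of those 5 arrays had a slope of 0.641, so bright transcripts read lower and dim transcripts read higher on it. Leaving this array out was an alternative fixed before the data were examined. Because it stood apart, values without it are given beside those over all 6 arrays for most lists and some genes. Other values of single genes are over all 6 arrays unless said.

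The comparison asked how treatment with mTORi-HDL altered gene expression in macrophages of the rejecting graft. Lists of cell division and T cell genes were lower in the treated samples and a list of connective tissue genes was higher. None of these lists passed with an estimated correlation, and no single gene passed the test over all genes. The 10 genes with the smallest p and a lower level, which did not pass adjustment, included several known from chromosome replication or mitosis, grouped here by hand and not by a test. They were Kif11, a motor of the mitotic spindle, Ube2c, an enzyme of mitotic exit, and Bub1b and Knl1 of the spindle checkpoint and kinetochore. The others were Cdc45 of the replication fork, Bora, a cofactor of Aurora A kinase, and the histone genes H2bc12 and H2bc18. H2bc12 had a log2 level of 3.74 ± 0.11 in treated and 6.59 ± 0.25 in untreated samples (SD, n = 3 each), and Kif11 had 4.38 ± 0.62 and 7.45 ± 0.19. Ube2c was lower by 2.24 on average (5.23 ± 0.27 against 7.47 ± 0.21), and Batf, a transcription factor of activated lymphocytes and dendritic cells, had 5.63 ± 0.58 against 8.20 ± 0.20. H2bc18 and Prr11, the last of the 10, had log2 fold changes of -2.57 and -2.83.

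The 10 genes with the smallest p and a higher level included Mmp12, the macrophage elastase, at 7.60 ± 0.52 in treated and 5.18 ± 0.38 in untreated samples (SD, n = 3 each). Lipid genes among them, grouped by hand and none past adjustment, were Lpl, lipoprotein lipase, at 6.72 ± 0.59 against 4.65 ± 0.55, and further Olr1, a receptor for oxidised lipoprotein, and Ch25h, cholesterol 25-hydroxylase. Olr1 had a log2 fold change of 2.18 and Ch25h one of 2.11. Tmem176b, Wfdc17, Cttnbp2nl, Ifitm6, Csf2rb2 and the matrix gene Dcn had log2 fold changes of 1.97 to 2.30. In limma's test 0 of the 22180 genes passed an adjusted p of 0.05, with a smallest adjusted p of 0.181 for H2bc12. An unadjusted p under 0.05 was found for 1029 genes (349 higher, 680 lower), where 1109 would be found by chance. The 3 arrays of one group lay above all 3 of the other for 1191 genes in the higher and 1226 in the lower direction, together 10.9% where chance gives 10%. With mTORi-HDL 1 left out the count past the threshold was again 0. The count at an unadjusted p under 0.05 was then 1547 (769 higher, 778 lower), and 787 genes were in both counts. The smallest adjusted p was then 0.0919, shared by H2bc12 and by Pltp, phospholipid transfer protein. The log2 fold change of Pltp was 2.99 ± 0.23 (SE) without that array and 1.71 ± 0.97 with it.

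**Figure D1:**
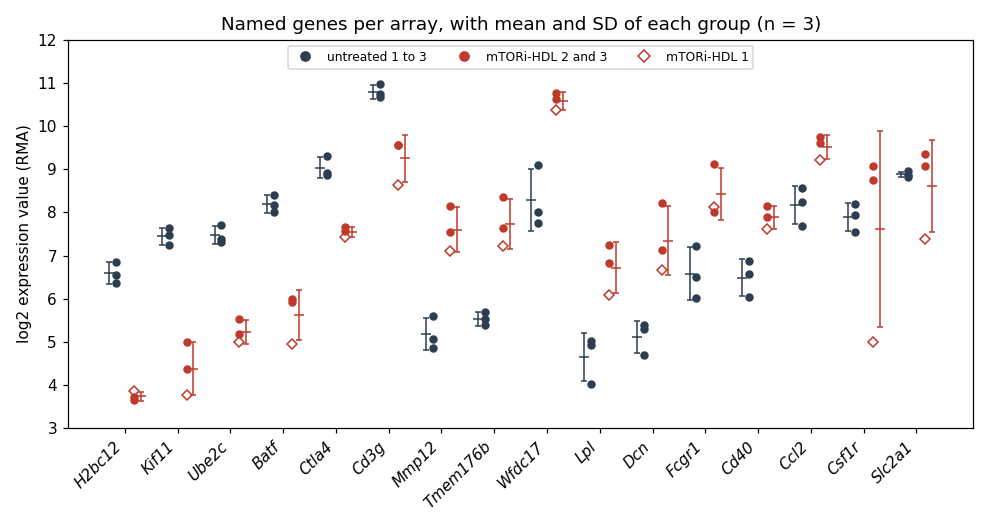
Log2 expression values of 16 genes on each array, with the mean and SD of each group (n = 3) beside the points; the open diamond is mTORi-HDL 1. H2bc12 lay at 3.74 in treated and 6.59 in untreated samples, while Csf1r lay at 5.00 on mTORi-HDL 1 and at 8.75 and 9.08 on the other treated arrays.

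The 30 gene lists fixed before the data were examined gave a clearer contrast for cell division than for any other pathway. Of 47 measured cell cycle genes, 45 were lower in treated samples, 29 of them at an unadjusted p under 0.05. Adjusted over the list alone 23 passed, all lower, while 0 passed over all genes. The mean of the list fell by 1.37 on the log2 scale in camera's test (adjusted p = 4.28e-33; adjusted p = 0.0954 with an estimated correlation). Bub1b had 4.58 ± 0.22 in treated and 6.78 ± 0.60 in untreated samples, and Cenpe, a kinetochore motor, had 4.21 ± 0.41 and 6.32 ± 0.46 (SD, n = 3 each). The list lay below the untreated mean by a similar amount on the treated arrays 2 and 3 (-1.02 and -1.16) and further on mTORi-HDL 1 (-1.94), against an SD of 0.22 among untreated arrays. Without mTORi-HDL 1 the mean change was -1.09 (adjusted p = 1.75e-24; adjusted p = 0.157 with an estimated correlation). Then 43 genes were lower and 4 higher, and adjusted over the list alone 24 passed as lower and 2 as higher.

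Compression of 1 array can move camera's result by itself, which bears on every list below. When arrays with no changed gene were simulated for this comparison, after the list results had been seen, with the slope and scatter of mTORi-HDL 1 given to 1 treated array, camera called the cell cycle, T cell, NK cell and oxidative phosphorylation lists lower in 20 of 20 simulations of 22180 genes. It called the mTOR pathway list lower in 15, the amino acid and one-carbon list in 8, glycolysis in 5, the B cell list in 4 and cholesterol synthesis in 2. Of the inflammatory lists it called lower antigen presentation and immediate-early genes in 20, interferon-stimulated genes in 19, cytokines in 17, pattern recognition genes in 12, regulatory macrophage genes in 4 and costimulatory ligands in 0. The pan-macrophage list was called lower in 16 and the tissue-resident macrophage list in 1. Ribosomal proteins were called lower in 20, lysosome genes in 14 and inflammatory monocyte genes in 13. Hypoxia genes were called lower in 5, dendritic cell markers in 4 and cholesterol efflux genes in 1. The mast cell, basophil and eosinophil list was called higher in 2, and the fibroblast and cardiomyocyte lists were called in 0. When the compressed array was left out, 0 of 29 unshifted lists were called on average over 10 simulations. The simulated genes varied independently of each other.

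T cell transcripts were abundant in these sorted cells and lower after treatment. All 19 measured T cell markers were lower in treated samples, 11 of them at an unadjusted p under 0.05. Adjusted over the list alone 9 passed, and over all genes 0. The list fell by 1.51 (camera, adjusted p = 6.65e-19; adjusted p = 0.313 with an estimated correlation). Cd3g, a chain of the T cell receptor complex, had 9.25 ± 0.54 in treated and 10.79 ± 0.16 in untreated samples, and Ctla4, an inhibitory receptor of T cells, had 7.55 ± 0.11 and 9.03 ± 0.25 (SD, n = 3 each). Cd6 and the kinase Zap70 had log2 fold changes of -1.49 and -1.20. Without mTORi-HDL 1 all 19 were still lower, 12 passed adjusted over the list alone, and the mean change was -0.97 (adjusted p = 3.38e-17; adjusted p = 0.0803 with an estimated correlation).

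Among NK and cytotoxic lymphocyte markers, 12 of 14 were lower, 3 at an unadjusted p under 0.05, with 1 passing adjusted over the list alone and 0 over all genes. This was Klrg1, at 3.66 ± 0.48 against 5.76 ± 0.53 (SD, n = 3 each). The NK list had a mean change of -0.75 (camera, adjusted p = 8.54e-05; adjusted p = 0.422 with an estimated correlation) and, without mTORi-HDL 1, of -0.35 (adjusted p = 0.0241; adjusted p = 0.338 with an estimated correlation). Gzmb, granzyme B, had 10.56 ± 0.73 against 11.61 ± 0.13. The 13 B and plasma cell markers had a mean change of -0.31 (camera, adjusted p = 0.0484; adjusted p = 0.531 with an estimated correlation), with 0 passing adjusted over the list alone or over all genes, and of -0.15 without mTORi-HDL 1 (adjusted p = 0.347). Of these, 1 was at an unadjusted p under 0.05, Ms4a1, the B cell surface protein CD20, with a log2 fold change of -0.83.

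Macrophage transcripts moved the other way on the treated arrays 2 and 3. Of 19 pan-macrophage markers 13 were higher over all arrays, 4 of them at an unadjusted p under 0.05 and 0 passing adjusted over the list alone or over all genes. The Fc receptors Fcgr1 and Fcgr3 had 8.43 ± 0.61 against 6.58 ± 0.61 and 7.24 ± 0.19 against 6.24 ± 0.37 (SD, n = 3 each). The lysosomal membrane protein Cd63 had a log2 fold change of 1.71. The list rose by 0.38 (camera, adjusted p = 0.0216; adjusted p = 0.649 with an estimated correlation). It lay at 0.65 and 1.25 above the untreated mean on treated arrays 2 and 3 and at -0.75 on mTORi-HDL 1. Without the latter it rose by 0.95, with 17 of 19 markers higher (adjusted p = 7.64e-11; adjusted p = 0.203 with an estimated correlation). The call was lost without mTORi-HDL 3 (adjusted p = 0.946), without mTORi-HDL 2 (0.226) and without untreated 3 (0.126). Csf1r, the receptor for macrophage colony-stimulating factor, was at 5.00 on mTORi-HDL 1, at 8.75 and 9.08 on the other treated arrays and at 7.89 ± 0.33 in untreated samples (SD, n = 3).

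Genes of tissue-resident macrophages rose by 0.36 as a list (camera, adjusted p = 0.0118; adjusted p = 0.362 with an estimated correlation), with 19 of 24 higher, 4 at an unadjusted p under 0.05 and 0 passing adjusted over the list alone or over all genes. The complement gene C1qb had 8.34 ± 0.34 against 7.34 ± 0.41 (SD, n = 3 each), C1qc had a log2 fold change of 0.77, and the mannose receptor Mrc1 had one of 1.19. The list rose by 0.51 without mTORi-HDL 1, while its median was lower (0.17 against 0.37) and 16 of 24 genes were higher, and 4 genes passed adjusted over the list alone (adjusted p = 0.000163; adjusted p = 0.247 with an estimated correlation). Inflammatory monocyte genes had a mean change of 0.07 and a median of -0.07 over 27 genes (camera, upward, adjusted p = 0.737). Ifitm6 and the lysozyme gene Lyz1 passed adjusted over the list alone, while 0 passed over all genes. Fn1, fibronectin, ranged from 4.53 to 9.54 across the treated arrays. The monocyte list rose by 0.45 without mTORi-HDL 1 (adjusted p = 0.00389; adjusted p = 0.315 with an estimated correlation), with a median of 0.12 and 16 of 27 genes higher. It lay at 0.05 on mTORi-HDL 2 and at 0.85 on mTORi-HDL 3, against 0.30 on untreated 2, so the groups overlapped. Ly6c2, the classical marker of these monocytes, was lower on treated arrays 2 and 3 (7.92 and 8.13) than in untreated samples (8.69 ± 0.17, SD, n = 3).

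Dendritic cell markers did not pass over all arrays on the values as deposited, with a mean change of 0.38 over 16 genes (camera, adjusted p = 0.126), and passed upward after quantile normalization (adjusted p = 0.0451) and cyclic loess (0.00161). Itgae, an integrin of cross-presenting dendritic cells, was lower at an unadjusted p under 0.05, with a log2 fold change of -1.11. Batf3, a factor of cross-presenting dendritic cells, passed adjusted over the list alone (7.50 ± 0.37 in treated and 5.85 ± 0.49 in untreated samples, SD, n = 3 each), against 0 over all genes. With mTORi-HDL 1 left out the dendritic cell list rose by 0.79 (camera, adjusted p = 5.62e-07, and adjusted p = 0.201 with an estimated correlation). Then 6 of its genes, among them Flt3, the receptor of a dendritic cell growth factor, passed adjusted over the list alone.

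Connective tissue transcripts were higher on each treated array. The 18 fibroblast and mural cell markers rose by 0.71 (camera, adjusted p = 1.31e-05; adjusted p = 0.0954 with an estimated correlation), and lay between 0.67 and 0.74 above the untreated mean on the 3 treated arrays. All 4 genes at an unadjusted p under 0.05 also passed adjusted over the list alone, and 0 passed over all genes. These were Dcn, decorin (7.34 ± 0.80 against 5.12 ± 0.37), Col1a2, a chain of type I collagen (7.86 ± 0.24 against 5.66 ± 1.14), Lum, lumican (5.10 ± 0.88 against 3.33 ± 0.25) and Rgs5, a pericyte gene (4.34 ± 0.26 against 3.19 ± 0.15; SD, n = 3 each). Without mTORi-HDL 1 the list rose by 0.73 (camera, adjusted p = 1.98e-06, and adjusted p = 0.157 with an estimated correlation). Its median change was 0.50 over all arrays and 0.39 without mTORi-HDL 1, with 15 and 14 of 18 genes higher. The mast cell, basophil and eosinophil list rose by 0.48 over 14 genes (camera, adjusted p = 0.00275; adjusted p = 0.349 with an estimated correlation). Its genes at an unadjusted p under 0.05 were the 3 genes Cma1, Fcer1a and Kit, with 0 passing adjusted over the list alone or over all genes. Its value without mTORi-HDL 1 was 0.46 (adjusted p = 0.00169; adjusted p = 0.201 with an estimated correlation). Cardiomyocyte markers rose by 0.28 over 21 genes (camera, adjusted p = 0.0484; adjusted p = 0.605 with an estimated correlation), and did not pass without mTORi-HDL 1 (adjusted p = 0.0904). The troponins Tnnc1 and Tnnt2 were the 2 at an unadjusted p under 0.05, and 0 passed adjusted over the list alone or over all genes. Mean changes were 0.37 for neutrophil markers, 0.34 for erythroid and platelet markers and 0.11 for endothelial markers. In camera's test over all arrays none passed (adjusted p = 0.146, 0.239 and 0.509, in that order). On mTORi-HDL 1 the neutrophil list lay at 0.87 (-0.01 and 0.23 on treated arrays 2 and 3). The erythroid and platelet list lay at 1.19 there (-0.04 and -0.12 on the other 2). Without mTORi-HDL 1 none of the 3 lists passed, with mean changes of 0.11, -0.08 and 0.04. In these 3 lists 0, 0 and 1 genes were at an unadjusted p under 0.05 over all arrays (Eng, an endothelial receptor), and 0 passed adjusted over the list alone or over all genes.

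**Figure D2:**
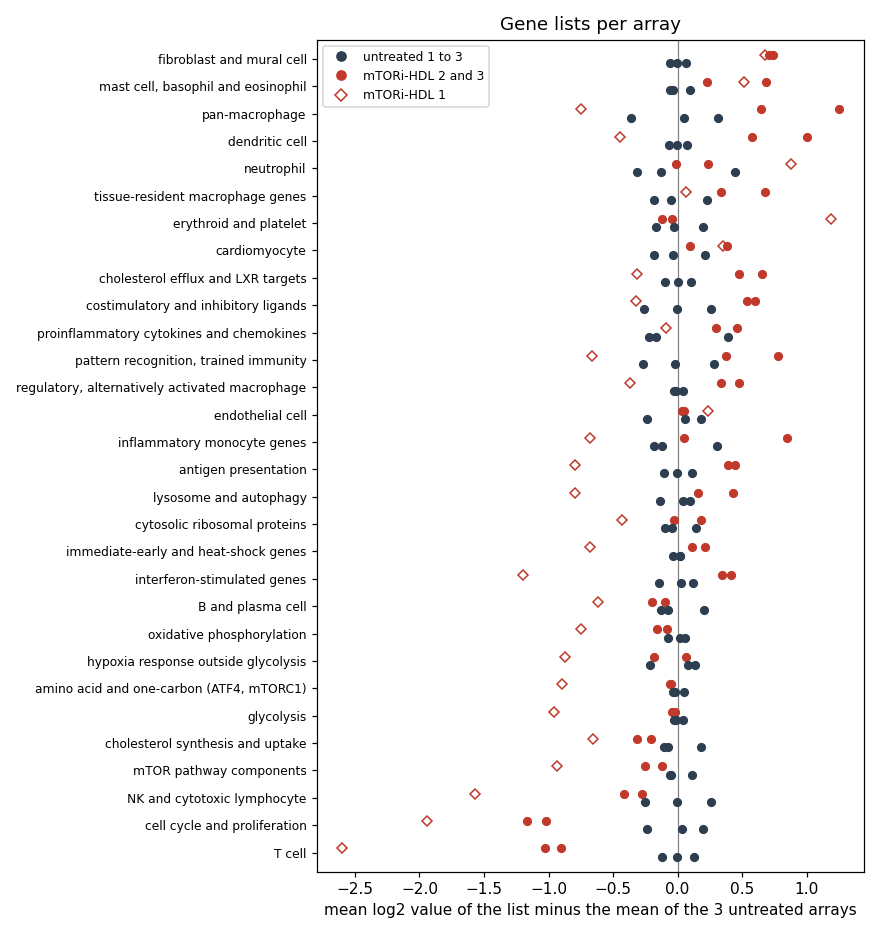
Mean log2 value of each of the 30 gene lists on each array, minus the mean of the 3 untreated arrays; the open diamond is mTORi-HDL 1. T cell and cell cycle lists lay below 0 on all treated arrays, and the fibroblast list lay at 0.67 to 0.74. The array mTORi-HDL 1 lay below the other treated arrays for interferon-stimulated genes (-1.20 against 0.41 and 0.34). It lay above them for erythroid and platelet markers (1.19 against -0.04 and -0.12).

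Genes of the drug's own pathway and of the metabolism it governs were lower over all arrays, mainly on mTORi-HDL 1. The 46 mTOR pathway components fell by 0.43 (camera, adjusted p = 8.54e-05; adjusted p = 0.362 with an estimated correlation). The list's changes were -0.93 on mTORi-HDL 1 and -0.25 and -0.12 on the other treated arrays. Of its members 5 were lower at an unadjusted p under 0.05, and 0 passed adjusted over the list alone or over all genes. Among them were Sesn3, an inhibitor of mTOR complex 1 (6.18 ± 0.95 against 7.66 ± 0.19), the S6 kinase Rps6kb2 (4.92 ± 0.84 against 6.25 ± 0.28), Pdpk1, a kinase upstream of Akt (5.92 ± 0.66 against 7.16 ± 0.37) and Tbc1d7, a subunit of the TSC complex (3.78 ± 0.26 against 4.72 ± 0.35; SD, n = 3 each). Without mTORi-HDL 1 the mean change was -0.18 and the list did not pass (camera, adjusted p = 0.0842). Over all arrays Sesn3, Rps6kb2, Pdpk1 and Tbc1d7 had log2 fold changes of -1.48, -1.34, -1.23 and -0.94. Without that array these were -0.95, -0.86, -0.86 and -1.06. Mtor itself had log2 fold changes of -0.14 ± 0.32 and, without that array, of 0.09 ± 0.27 (SE).

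The 21 glycolysis genes fell by 0.34 (camera, adjusted p = 0.0394; adjusted p = 0.605 with an estimated correlation), with changes of -0.96 on mTORi-HDL 1 and of -0.04 and -0.02 on the other treated arrays. Without mTORi-HDL 1 the mean change was -0.03 and camera's direction turned upward (adjusted p = 0.993). Pfkfb3, which makes an activator of phosphofructokinase, was lower and Hk3, a hexokinase of myeloid cells, higher at an unadjusted p under 0.05, with log2 fold changes of -1.29 and 1.10, and 0 passed adjusted over the list alone or over all genes. Without mTORi-HDL 1 Hk3 passed adjusted over the list alone (log2 fold change 1.56), and Pfkfb3, with a log2 fold change of -0.81, did not. Oxidative phosphorylation genes fell by 0.33 over 51 genes (camera, adjusted p = 0.000894; adjusted p = 0.362 with an estimated correlation), with Ndufs7 of complex I as the 1 gene at an unadjusted p under 0.05 and 0 passing adjusted over the list alone or over all genes. The mean change without mTORi-HDL 1 was -0.12 (adjusted p = 0.0842). Amino acid and one-carbon genes of the ATF4 response fell by 0.33 (camera, adjusted p = 0.0424; adjusted p = 0.349 with an estimated correlation), and their mean change without mTORi-HDL 1 was -0.06 (adjusted p = 0.602). After quantile normalization the oxidative phosphorylation list (adjusted p = 0.214) and the ATF4 list (0.352) did not pass. The serine synthesis genes Psph, Phgdh and Psat1 were the 3 of 31 at an unadjusted p under 0.05, all lower, with 0 passing adjusted over the list alone or over all genes. Cytosolic ribosomal proteins had a mean change of -0.09 over 54 genes (camera, adjusted p = 0.285), and of 0.08 without mTORi-HDL 1. Over all arrays 2 of them were at an unadjusted p under 0.05, and 0 passed adjusted over the list alone or over all genes. Hypoxia genes outside glycolysis had a mean change of -0.33 over 16 genes (camera, adjusted p = 0.126). Without mTORi-HDL 1 it was -0.06, with 8 genes higher and 8 lower. Neither list passed with all arrays or without mTORi-HDL 1. In the hypoxia list the prolyl hydroxylase Egln3 had 3.73 ± 0.31 in treated and 5.28 ± 0.59 in untreated samples (SD, n = 3 each), with 0 genes passing adjusted over the list alone or over all genes and 2 at an unadjusted p under 0.05.

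Sterol genes were covered by separate lists for synthesis and uptake and for efflux. Cholesterol synthesis and uptake genes fell by 0.39 over 19 genes, 17 of them lower (camera, adjusted p = 0.000894; adjusted p = 0.262 with an estimated correlation), and by 0.26 without mTORi-HDL 1 (adjusted p = 0.0185; adjusted p = 0.247 with an estimated correlation). The synthesis enzymes Ebp and Sc5d had log2 fold changes of -0.68 and -0.95, the 2 at an unadjusted p under 0.05, and 0 passed adjusted over the list alone or over all genes. Cholesterol efflux and LXR target genes had a mean change of 0.27 and a median of 0.12 over 18 genes (camera, adjusted p = 0.167; 0.0327 after quantile normalization and 0.00406 after cyclic loess, both upward), and Lpl passed adjusted over the list alone, against 0 over all genes. Apoe, the lipid carrier, had 6.33 ± 0.25 in treated and 5.41 ± 0.13 in untreated samples (SD, n = 3 each). Nr1h3 and Scd1 of the same list were lower, with log2 fold changes of -0.65 and -1.67, neither at an unadjusted p under 0.05. Without mTORi-HDL 1 these were -0.46 and -0.57. The efflux list rose by 0.56 without mTORi-HDL 1, with 2 genes passing adjusted over the list alone (adjusted p = 9.17e-05; adjusted p = 0.157 with an estimated correlation). Lysosome and autophagy genes had a mean change of -0.07 and a median of 0.06 over 34 genes (camera, downward, adjusted p = 0.846). Without mTORi-HDL 1 they rose by 0.29 (adjusted p = 5.45e-05; adjusted p = 0.230 with an estimated correlation). Gabarapl1, an autophagy gene with the smallest p of the list, had a log2 fold change of -0.99, and Lamp2, a lysosomal membrane protein, had 9.91 ± 0.40 in treated and 9.01 ± 0.11 in untreated samples (SD, n = 3 each). Of the 3 genes at an unadjusted p under 0.05 in this list 0 passed adjusted over the list alone or over all genes.

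Inflammatory gene lists did not pass over all arrays on the values as deposited. Proinflammatory cytokines and chemokines had a mean change of 0.22 over 41 genes (camera, adjusted p = 0.0612), with 7 genes higher and 0 lower at an unadjusted p under 0.05 and 0 passing adjusted over the list alone or over all genes. Ccl2, which recruits monocytes, had 9.52 ± 0.28 in treated and 8.17 ± 0.44 in untreated samples, and Ccl12 had 9.75 ± 0.65 and 7.91 ± 0.53 (SD, n = 3 each). Of 22 costimulatory and inhibitory ligands 3 were higher at an unadjusted p under 0.05 (mean change 0.27, adjusted p = 0.146). Of these, Cd40, a receptor for T cell help, at 7.89 ± 0.27 against 6.49 ± 0.43, and Pirb, an inhibitory receptor of myeloid cells, at 9.09 ± 0.34 against 6.99 ± 0.95, passed adjusted over the list alone, and 0 passed over all genes. Pattern recognition and trained immunity genes had a mean change of 0.16 and a median of -0.02 over 32 genes (upward, adjusted p = 0.620). Interferon-stimulated genes had a mean change of -0.15 over 35 genes (adjusted p = 0.145). Antigen presentation genes had one of 0.01 over 23 (adjusted p = 0.825) and regulatory macrophage genes one of 0.15 over 31 (adjusted p = 0.509). Immediate-early and heat-shock genes had one of -0.12 over 30 (adjusted p = 0.366), with 15 genes higher and 15 lower. In these 5 lists 2, 2, 0, 3 and 4 genes were at an unadjusted p under 0.05, in the order given, and 0 passed adjusted over the list alone or over all genes.

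With all 6 arrays kept, the cytokine list passed upward after quantile normalization (adjusted p = 0.00327). After cyclic loess, chosen after the data were seen, the lists of cytokines (adjusted p = 0.000607), antigen presentation (0.00109), pattern recognition (0.00527), costimulatory ligands (0.00745) and immediate-early genes (0.0209) passed upward. Without mTORi-HDL 1 these 7 lists all passed upward in camera's test. Cytokines and chemokines rose by 0.38, costimulatory ligands by 0.57 and pattern recognition genes by 0.58 (adjusted p = 4.28e-05 for each; adjusted p = 0.238, adjusted p = 0.203 and adjusted p = 0.223 with an estimated correlation). The cytokine list lay at 0.30 and 0.46 on treated arrays 2 and 3 and at 0.39 on untreated 2, so the groups overlapped. Interferon-stimulated genes rose by 0.38 (adjusted p = 4.93e-06; adjusted p = 0.201 with an estimated correlation) and antigen presentation genes by 0.42 (adjusted p = 2.97e-06; adjusted p = 0.203 with an estimated correlation). Regulatory macrophage genes rose by 0.41 (adjusted p = 0.0302), with a median of 0.10 and 17 of 31 genes higher, and immediate-early genes by 0.16 (adjusted p = 0.0203), each with adjusted p = 0.203 with an estimated correlation. The interferon and immediate-early lists thereby turned from a lower to a higher mean. Fos, an immediate-early transcription factor, had a log2 fold change of 2.08 ± 0.26 (SE) and Mx2, an antiviral gene, one of 1.76 ± 0.29, both without that array. The pan-macrophage markers were higher by 0.95 in the same arrays and the T cell markers lower by 0.97.

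Of a fixed panel of 32 genes of mTOR signalling, glycolysis and macrophage states, 31 were measured, 5 of them at an unadjusted p under 0.05 and 10 without mTORi-HDL 1, with 0 passing over all genes in limma's test either way. In all arrays Cd40, Mrc1 and Apoe were higher and Ldha, Tgfb1 and Ly6c2 lower than in every array of the other group. Of these, Ldha was dim, at 4.09 ± 0.18 in treated and 4.61 ± 0.06 in untreated samples (SD, n = 3 each), where array medians were 3.85 to 4.22. Its unadjusted p in limma's test was 0.0699, so its fall is weak evidence on this enzyme. Among inflammatory products Tnf had 8.34 ± 0.75 in treated and 8.03 ± 0.70 in untreated samples, Il1b had 9.66 ± 1.85 and 9.79 ± 0.50, and Il6 had 3.72 ± 1.47 and 4.02 ± 1.41 (SD, n = 3 each). Il1b lay at 7.54 on mTORi-HDL 1 and at 10.51 and 10.94 on the other treated arrays, and its log2 fold change without mTORi-HDL 1 was 0.93 ± 0.34 (SE). That of Tnf was then 0.68 ± 0.45, and Il6 lay at 3.13 on mTORi-HDL 1 and at 2.64 and 5.39 on the other treated arrays. Arg1 had 6.32 ± 1.80 and 5.44 ± 0.49, and Nos2 had 5.60 ± 0.36 and 5.53 ± 1.37 (SD, n = 3 each), with log2 fold changes of 0.96 and 0.27 without mTORi-HDL 1. Clec7a, the beta-glucan receptor of trained immunity, had 7.37 ± 2.44 and 7.68 ± 0.64, and its log2 fold change turned from -0.31 to 0.90 without that array. Slc2a1, the main glucose transporter of activated leukocytes, had 8.61 ± 1.07 and 8.88 ± 0.07 (log2 fold change 0.34 without mTORi-HDL 1), and Hk2 had 5.74 ± 0.22 and 5.76 ± 0.14. Il10 had 6.58 ± 1.73 and 8.18 ± 0.78, with a log2 fold change of -0.65 without that array.

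In camera's preset test 14 of the 30 lists passed over all arrays, 5 of them upward, and 19 without mTORi-HDL 1, 15 of them upward, with 8 lists passing in both in the same direction. With an estimated correlation 0 lists passed camera in either case, with 4 and 7 at an unadjusted p under 0.05, and fry called 2 (the cell cycle list lower and the fibroblast list higher) and, without mTORi-HDL 1, 6. For a single value, 3 arrays against 3 allow no exact permutation p below 0.1.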

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

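Cyclic loess and the 4 settings that leave out mTORi-HDL 1 together with another choice were chosen after seeing the data. The count of genes past limma's adjusted p of 0.05 stayed at 0, except with array weights, which gave mTORi-HDL 1 a weight of 0.149 and called 1 gene (H2bc12, log2 fold change -2.89, adjusted p = 0.0200). An unadjusted p under 0.05 with a fold of at least 1.5 held for 1028 genes. The count at an unadjusted p under 0.05, 1029, became 635 among genes above the median brightness (fewer genes tested), 1768 with array weights, 1702 over all probe sets (more features tested) and 615 to 1547 with 1 array left out (615 without untreated 3, 655 without untreated 2, 1547 without mTORi-HDL 1). The count of called lists, 14, became 0 with an estimated correlation, 2 with fry and 9 without shared members, and without mTORi-HDL 1 it was 0 with an estimated correlation and 6 with fry, and it ranged from 11 to 19 with 1 array left out. The cell cycle list kept its call in all settings but the estimated correlation (adjusted p = 0.0954, and 0.157 without mTORi-HDL 1), as did the fibroblast list (0.0954 and 0.157), with ranges of 3.23e-37 to 1.75e-24 and 1.98e-06 to 0.000435 when 1 array was left out. The T cell list lost it there (0.313 and 0.0803) and with fry over all arrays (0.252), with a range of 1.67e-18 to 6.88e-16. With fry it passed as lower when mTORi-HDL 1 was left out (0.0118). The mTOR pathway list lost it with an estimated correlation (0.362), with fry (0.473) and without mTORi-HDL 1 (range 6.38e-06 to 0.0842; 0.247 with an estimated correlation, 0.215 with fry, 0.0998 among bright genes). Glycolysis lost it with median centring (0.0826), quantile normalization (0.214), filters at the median (0.144) and 25th percentile (0.113), array weights (0.846), an estimated correlation (0.605), fry (0.569), cyclic loess (0.364) and without untreated 2 (0.0707). Without mTORi-HDL 1 it turned upward (0.993, range 0.00417 to 0.993; 0.994 with an estimated correlation) or stayed lower (0.934 with fry, 0.808 among bright genes). The pan-macrophage list lost it with trend and robust (0.0618), ranks (0.0772), an estimated correlation (0.649), fry (0.569), unshared members (0.0705) and, without mTORi-HDL 1, with an estimated correlation (0.203) or fry (0.143), with a range of 7.64e-11 to 0.946. Lists that turned from lower to higher past the threshold were lysosome genes (array weights 0.000377, without mTORi-HDL 1 5.45e-05, cyclic loess 0.0248, bright genes without that array 0.000361, range with 1 array left out 5.45e-05 to 0.929), interferon-stimulated genes (array weights 0.00144, without it 4.93e-06, bright genes without it 0.000189, range 4.93e-06 to 0.431, but lower past the threshold without mTORi-HDL 2, 0.00187, mTORi-HDL 3, 0.00600, or untreated 1, 0.0497) and immediate-early genes (without it 0.0203, cyclic loess 0.0209, fry without it 0.0468, bright genes without it 0.0464, range 0.0203 to 0.431). Beyond the cases named with fewer or more features or arrays, the cause was not tested. Of 660 list values 476 kept their side of the threshold, some with another sign, and 57 in all changed sign. Of 2605 values of named genes 75 changed sign, none past the threshold. The labels do not say whether the replicate numbers pair the arrays. Deviations of same-numbered arrays correlated at 0.136, 0.135 and -0.024. Differently numbered arrays were not compared, so these values cannot show that pairing is absent. A replicate block gave 0 genes past the threshold, 1183 at an unadjusted p under 0.05 and 10 lists, without the pan-macrophage list (adjusted p = 0.0524). No signal over background was used here, so dim genes carry an unknown share of noise.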

Other observations

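The families of genes in the first 2 paragraphs, the comparison of H2-Ea and most tests below were chosen after the data were seen, and the comparisons with random lists of matched brightness and with other groupings of the arrays were set down after the list results but before their own values were seen. Of 7 gene families, 3 passed camera's test (limma) over all arrays, without mTORi-HDL 1 and after cyclic loess, in the same direction each time. Because the families were picked on these data, these calls are no independent support. The histone family holds H2bc12 and H2bc18, named above among the genes with the smallest p. Replication-dependent histone genes were lower in 17 of 25 cases, with a mean log2 change of -0.87 and a median of -0.32 (adjusted p = 7.38e-06; adjusted p = 0.0806 with an estimated correlation). Without mTORi-HDL 1 the mean was -0.76 (adjusted p = 0.000203; adjusted p = 0.207 with an estimated correlation). H1f5, a linker histone, had 4.25 ± 1.52 in treated and 8.72 ± 0.63 in untreated samples, and H2ac10 had 6.87 ± 0.43 and 8.82 ± 0.83 (SD, n = 3 each). Chemokine receptors were lower in 12 of 15 cases, with a mean change of -0.76 (adjusted p = 8.14e-05; adjusted p = 0.0806 with an estimated correlation) and of -0.57 without mTORi-HDL 1 (adjusted p = 0.0132; adjusted p = 0.207 with an estimated correlation). The lower ones included Ccr8 (4.73 ± 1.44 against 8.24 ± 0.66), Cxcr6 (5.66 ± 0.99 against 8.39 ± 0.33) and Cxcr3 (6.29 ± 0.75 against 8.30 ± 0.42), receptors of activated T cells, while the monocyte receptor Ccr2 had a log2 fold change of -0.06, and of 0.76 without mTORi-HDL 1.

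Complement genes were higher in 9 of 11 cases, with a mean change of 0.52 (adjusted p = 0.0344; adjusted p = 0.382 with an estimated correlation) and of 1.06 without mTORi-HDL 1 (adjusted p = 5.97e-08; adjusted p = 0.207 with an estimated correlation). C4b lay at 7.68 and 9.06 on treated arrays 2 and 3, at 4.29 on mTORi-HDL 1 and at 5.66 ± 0.32 in untreated samples (SD, n = 3). Cathepsins (mean change -0.02, median 0.14, test upward, adjusted p = 0.839), matrix metalloproteinases (0.34, adjusted p = 0.0687), small nucleolar RNAs (-0.12, adjusted p = 0.156) and membrane-spanning 4-domain genes (0.01, adjusted p = 0.839) did not pass over all arrays. Cathepsins passed upward without mTORi-HDL 1, with a mean change of 0.26 and 14 of 18 higher (adjusted p = 0.0151; adjusted p = 0.207 with an estimated correlation).

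T cell and cell cycle transcripts were lower together. The compressed array alone does not account for this: on treated arrays 2 and 3 the highest list mean lay 0.79 below the lowest untreated one for T cells (untreated SD 0.12) and 0.78 below for the cell cycle (SD 0.22). Fewer T cells in the sorted material stays an open explanation: 14 of 19 markers (73.7%, where chance gives 10% for independent genes) were lower on both of these arrays than on all untreated arrays, but this count restates the pattern and the markers varied together. None of the 19 belongs to another list, and a macrophage gate is meant to exclude T cells, yet Cd3d, Thy1, Cd3g and Cd3e stood at 11.40, 11.07, 10.79 and 10.58 in untreated samples, above 99% of genes. Whether T cell loss is the whole source of the cell cycle fall cannot be told apart from slower division of macrophages. The 2 falls differed by -0.12 without mTORi-HDL 1, with a standard error of 0.15 over genes. That error treats genes as independent, though the markers varied together, so it understates the uncertainty.

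The mTOR pathway, glycolysis and oxidative phosphorylation lists passed as lower over all arrays and did not pass without mTORi-HDL 1, though their means stayed lower. That these lists were not called without that array was known when the test was set down. The compressed range may account for the first 2: among 10000 random lists of matched brightness the mTOR list's deviation on that array stood at percentile 25.5 and that of glycolysis at 19.7. Oxidative phosphorylation stood at 99.9, less reduced than genes as bright (-0.75 against a median of -1.45), so brightness alone does not predict its value and the explanation stays open for it. An effect of the treatment on the macrophages also stays open. It was not told apart from a changed mix of sorted cells. Without mTORi-HDL 1 the T cell list was lower by 0.97 and the pan-macrophage list higher by 0.95. Without that array the mean change was -0.0316 for glycolysis and -0.18 for the mTOR list. The standard errors over genes were 0.11 and 0.07, and they treat the genes as independent.

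H2-Ea, a class II gene that BALB/c mice express and C57BL/6 mice do not, lay at 7.58, 10.14 and 9.67 in treated and at 4.43, 6.60 and 3.70 in untreated samples, and did not pass limma's test (adjusted p = 0.696). H2-Ea differed by 3.75 more than the mean of H2-Aa, H2-Ab1 and H2-Eb1, which both strains express (SE 0.91 over arrays). The exact permutation p was 0.1, two-sided, the smallest that 3 arrays against 3 allow. H2-Ea was picked for its values, so this excess cannot exclude a general rise of class II genes. A candidate explanation is that more of the sorted cells were of donor origin, or that donor RNA had been taken up, which was not tested. The hypothesis was formed on these data, which therefore cannot decide it.

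With 3 arrays against 3 there are 10 groupings, too few for a share under 0.05. The real grouping gave 0 genes past the adjusted threshold, and the highest of the others gave 0, so all 10 gave as many. It gave 1029 genes at an unadjusted p under 0.05, where the highest other gave 1156 and 2 of 10 gave as many. It gave 14 called lists, where the highest other gave 19 and 7 of 10 gave as many. Every grouping holds mTORi-HDL 1 on one side. In the simulations with a compressed array 11.7 of 29 unshifted lists were called on average. The list counts therefore cannot separate the treatment from that array.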
